A study of Rattus norvegicus with 9 samples.

How the data were processed

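Gene expression was measured on 9 2-colour Agilent oligonucleotide arrays, each carrying 20500 gene probes and 1075 positive and negative control probes. The labels name 3 cell types from adult female Fischer rats: cultured olfactory ensheathing cells (cOEC, glia of the olfactory nerve grown from the olfactory nerve layer), cultured Schwann cells (SC, glia of the sciatic nerve) and the olfactory nerve layer dissected directly from the bulb (nOEC, called native ensheathing cells by the labels). Per the labels' protocols, each RNA came from 1 culture made from a pool of 4 rats, or from nerve layers pooled from 4 rats, and 500 ng of it was amplified and labelled. Cultured ensheathing cells had grown for 3.5 weeks and Schwann cells for 2 weeks, so that cell type and culture time differ together.

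Every pair of cell types was hybridised directly on 3 arrays, numbered replicates 1 to 3, with the dyes reversed on replicate 2. Each cell type thus lies in Cy5 on 3 arrays and in Cy3 on 3 arrays, which gives 6 channels per cell type and 18 channels in all. The series describes the design as a factorial one made of direct comparisons, and the fit used here follows it.

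The deposited scanner files hold spot intensity and local background intensity in both channels on the linear scale, measured with Agilent Feature Extraction 7.5.1 per the file headers. The same deposited files give the scanner software's log10 ratio of Cy5 over Cy3 after its own background subtraction and dye normalization, and flags for spots well above background, saturated spots and outlier spots, per the file headers. The deposited series matrix holds log2 ratios of Cy5 over Cy3 for the 20500 gene probes. Its scale and direction were found by setting each column against the scanner values, with Pearson's r across probes of 0.880 to 0.941 against the scanner log ratio and 0.980 to 0.994 against the loess ratio computed here. Which background correction and normalization the authors applied to that matrix is not given in the sources used here beyond the name limma, and its column medians lay near 0: 0.0061, 0.0097 and -0.0016 for cOEC against SC, 0.0059, 0.0074 and -0.0034 for cOEC against nOEC, and -0.0058, -0.0063 and 0.0084 for SC against nOEC, in the order of the replicates. The authors' deposited tables of log2 fold changes (SC over cOEC and nOEC over cOEC) equal a least-squares fit of all 9 matrix columns to within 5e-08, and the deposited p-value columns beside them come from a test whose name is not given in the sources used here.

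The analysis here started from the mean spot signals and median local backgrounds. Background was corrected with normexp (offset 50) and each array was normalized by loess, with control spots and outlier spots given weight 0, in limma 3.58.1 under R 4.3.3 with statmod 1.5.0. Control probes were then left out, as were values from outlier spots. A probe was kept if it was well above background in at least 3 of the 6 channels of at least 1 cell type, which held for 16945 probes. Where several kept probes carried 1 gene name, the one with the highest mean intensity stood for the gene, leaving 16805 genes.

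Of the 20500 gene probes, 2473 were listed by a RefSeq transcript accession and 2399 of these were matched to a current symbol in the RefSeq gene table of the GRCr8 assembly. A further 1519 probes were named through the symbol in their description, and 16582 have no symbol here. Among the latter, 174 probes carry a description that names a member of a gene list, for 122 different members, and such genes are called "named by its description". Probes carried 3760 different symbols, 153 of them on several probes. Of the 133 such symbols among the probes tested, 0 were called in opposite directions by their probes between cOEC and SC, 3 between cOEC and nOEC, and 2 between SC and nOEC. The genes tested include 3120 official symbols, and a "gene" without one is a probe.

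All 9 arrays entered 1 limma fit of the log2 ratios with 3 parameters: cOEC over SC, nOEC over SC and a dye term. This left 6 residual degrees of freedom, to which empirical Bayes moderation added 3.24. Each comparison rests on its 3 direct arrays and on the 6 arrays that link the cell types indirectly. Tests were 2-sided, p-values were adjusted by Benjamini and Hochberg over the 16805 genes, and a gene counts as changed at an adjusted p under 0.05. Errors printed with log2 ratios are standard errors of that fit, which uses 9 arrays. A gene in 0 of the 6 channels of a cell type well above background has only a bound there, given as "at least N-fold" between channel means after loess and Aquantile, each dim channel being set to no less than the lowest signal well above background on its array.

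The 25 gene lists were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over 75 tests of list and comparison. Camera with a correlation estimated for each list and fry were run as alternatives. Members past the threshold were counted over all genes and also adjusted over the list alone. Genes named in the text follow a fixed rule: per comparison, the 12 largest positive and the 12 largest negative log2 ratios among official symbols past the threshold that went the same way on all 3 direct arrays, and, per list and comparison, up to 4 members past the threshold with the largest ratios, or the 2 brightest members where none passed. Some genes that this rule names are not reported here, in the text or the figures. The comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Names for probes were settled before expression values were looked at by gene.

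Signal over background set the depth. The median background-corrected signal per channel ran from 94.7 to 150, against median backgrounds of 37 to 60. Between 61.0% and 79.0% of gene probes per channel were well above background (68.7% to 79.0% in cOEC, 61.0% to 73.5% in SC, 61.6% to 78.7% in nOEC). Saturated gene probes numbered 0 to 12 per channel and were kept, and outlier spots numbered 3 to 71 per array. The number of arrays limits the precision.

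The fit was tested on simulated data after a first pass over the real arrays, with spread, dye effect and intensities taken from them. Between cOEC and SC it recovered 41.8%, 85.1% and 98.5% of genes given log2 changes of 0.5, 1 and 2 (67, 67 and 66 genes), with 9 false calls, 5.66% of all calls. Between cOEC and nOEC it recovered 37.3%, 83.6% and 100% of such genes, with 8 false calls (5.16%). Between SC and nOEC, where nothing was changed, it made 0 calls among 16805 genes. The offset of 50 shrinks ratios of dim genes: median estimates for the 3 sizes were 0.26, 0.48 and 1.37 between cOEC and SC with it, and 0.51, 1.07 and 2.08 with an offset of 0. Log2 ratios printed in the text therefore understate the change of dim genes. A simulated set of 30 changed genes gave a camera p of 8.3e-98 and an unchanged set of 30 a p of 0.056 between cOEC and SC. The noise was drawn separately for each gene and array, with no RNA shared between arrays and no correlation between genes. The false calls therefore do not measure what either would add in the real data.

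The fit within day 2 used 3 arrays, which also required leaving out the dye term. The scanner log ratios and the series matrix values brought their own processing, in place of both background correction and loess. Apart from these, the alternatives changed 1 choice at a time. They were no background correction, normexp with offset 0, the scanner log ratios, median centring in place of loess, Aquantile after loess, the series matrix values, no filter on dim probes, a filter asking for all 18 channels, every probe kept, no dye term, only the 3 direct arrays, a separate-channel fit, array weights, a block for the replicate number, a block for the day of image extraction, stricter thresholds, each array and each replicate number left out, other list tests, and overlaps from arrays of different replicate numbers. The day of extraction, in order from 1 to 4, is given by the file headers and was the batch tested. Day 1 holds only cOEC and SC replicate 1, and day 3 only SC and nOEC replicate 1. On those days the day cannot be told from the array. Lists restricted to members named by a symbol, and fits within the days that hold several comparisons, were added after the data had been seen.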

Results

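The data compare 3 kinds of rat glia on 9 arrays: cultured olfactory ensheathing cells (cOEC), cultured Schwann cells (SC) and the acutely dissected olfactory nerve layer that holds native ensheathing cells (nOEC). Each pair of cell types shares 3 arrays, and every cell type fills 6 of the 18 channels. Log2 ratios are given as cOEC over SC, cOEC over nOEC and SC over nOEC, with the standard error of the fit over 9 arrays and limma's adjusted p. Of 16805 genes tested, 2409 differed between cOEC and SC, 6042 between cOEC and nOEC and 6277 between SC and nOEC. These counts treat the arrays as independent, and the labels do not say whether arrays of 1 replicate number share RNA. With a block for that number, 1046, 5944 and 4359 genes differed. Across genes, which are not independent replicates, Pearson's r between the 3 direct arrays of a comparison was 0.37 to 0.75 for cOEC and SC, 0.64 to 0.85 for cOEC and nOEC, and 0.68 to 0.80 for SC and nOEC. With the fitted dye effect taken out, r was 0.67 to 0.83, 0.85 to 0.94 and 0.79 to 0.90.

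The comparison of cOEC with SC asks how the cultured glia of the olfactory system and of peripheral nerve differ. In cultured ensheathing cells, Ccdc80, a matrix-associated secreted protein, was higher by a log2 ratio of 6.02 ± 0.16, fibronectin (Fn1) by 4.37 ± 0.19, the matricellular factor Ccn2 by 4.39 ± 0.24 and complement C3 by 4.22 ± 0.30. Schwann cells had more RNA for the low-affinity neurotrophin receptor Ngfr (-2.77 ± 0.25), the monocyte chemokine Ccl2 (-3.09 ± 0.28) and the neurofilament Nefl (-2.28 ± 0.28). In all, 1395 genes were higher in cOEC and 1014 lower, 14.3% of those tested. Of these calls, 57.9% were higher, against 79.0% (1965 higher and 523 lower) under median centring in place of loess. A block for the replicate number kept 1035 of the 2409 calls, and 58 of the 80 called results for named genes.

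Among the 12 largest increases were also proenkephalin (Penk, an opioid peptide precursor, 4.68 ± 0.14), the peripheral myelin protein Pmp22 (4.22 ± 0.40), the protease inhibitor A2m (3.92 ± 0.49) and the calcitonin receptor partner Ramp3 (3.87 ± 0.19). They also held the transcription factor Cebpd (3.77), transferrin (Tf, 3.67) and the secreted protein Mia (3.51). Their adjusted p in limma lay between 3.1e-07 and 0.00054. The 12 largest decreases included the growth cone protein Gap43 (-3.11 ± 0.71, limma's adjusted p = 0.016), the G protein subunit Gng11 (-2.90), galectin Lgals1 (-2.22), the endothelin receptor Ednrb (-2.18) and the lysophosphatidic acid receptor Lpar1 (-2.12). Adenylate cyclase Adcy5 (-2.08), the small heat shock protein Cryab (-2.03), the fatty acid binding protein Fabp5 (-1.96) and the receptor phosphatase Ptprf (-1.83) completed them. By the rule that named them, all 24 genes went the same way on the 3 direct arrays. Over all calls, 1275 of the 1395 higher genes and 900 of the 1014 lower ones did so. Gap43 lost its call without cOEC and SC replicate 2 (-2.78, adjusted p = 0.079) or replicate 3 (-2.65, adjusted p = 0.086).

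**Figure D1:**
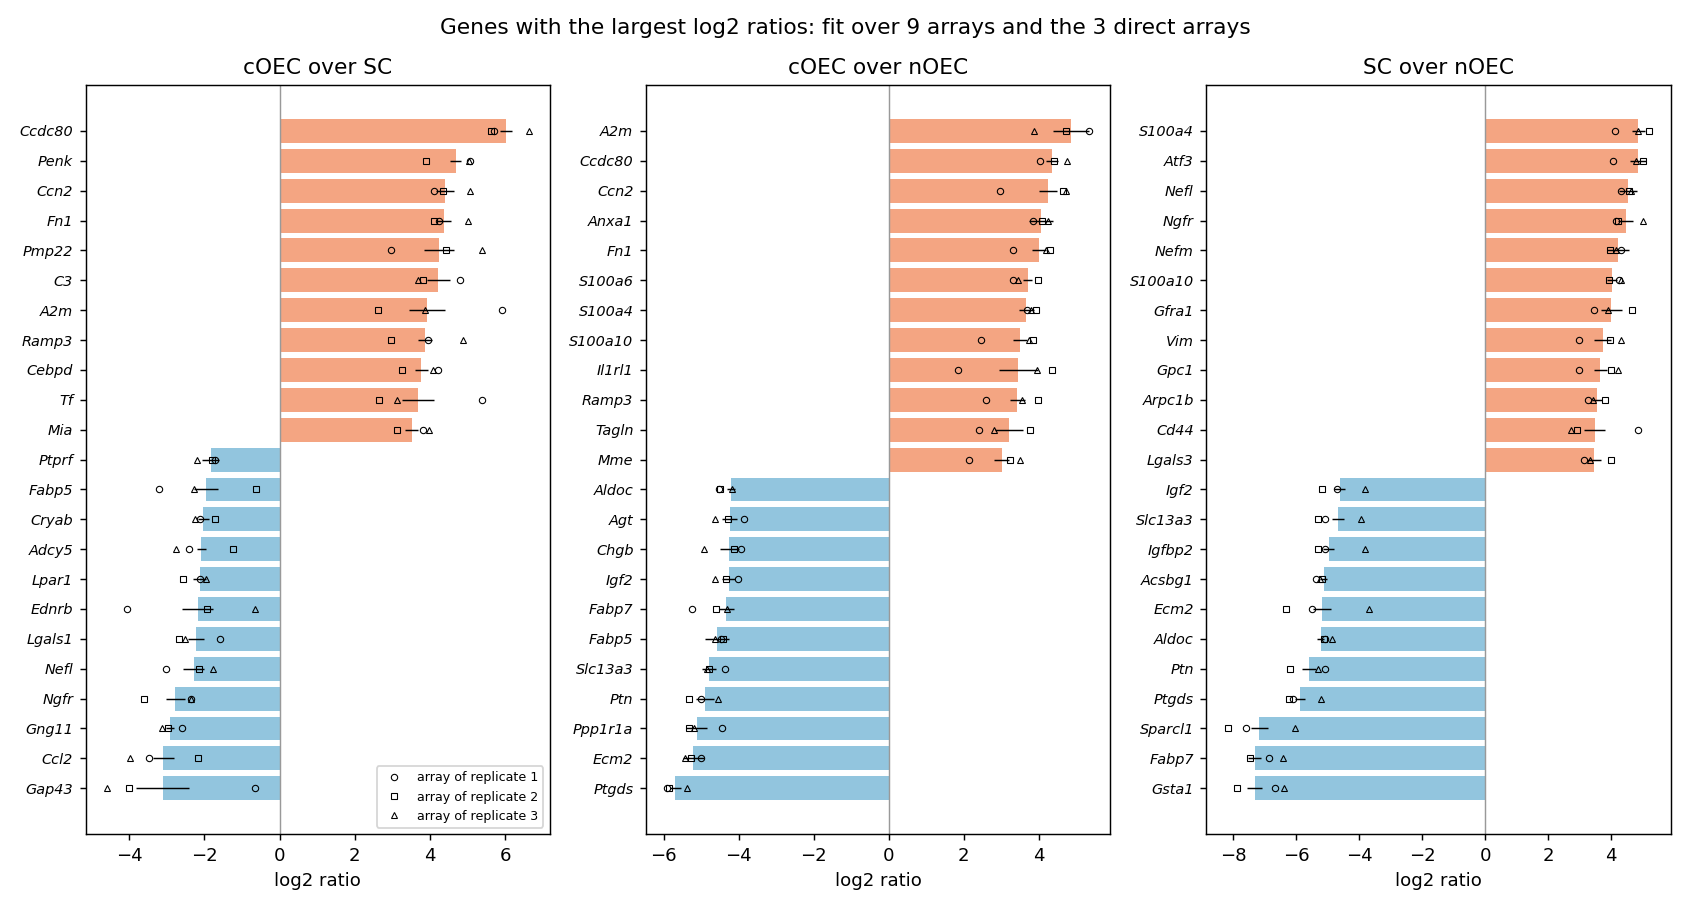
Log2 ratios of genes with the largest differences among official symbols in each of the 3 comparisons. Bars show the ratio from the fit with its standard error over 9 arrays, from Ccdc80 at 6.02 in cOEC over SC to Gsta1 at -7.31 in SC over nOEC. Markers show the 3 direct arrays, all on the same side of 0 as their bar by the rule that picked the genes.

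Glial identity genes went both ways between the cultures. Of 15 ensheathing cell markers, 7 were higher in cOEC, 5 lower and 3 not past the threshold (8 higher and 5 lower adjusted over the list alone). Brain lipid binding protein Fabp7 (2.98 ± 0.21) and apolipoprotein D (Apod, 2.50 ± 0.15) were higher, and Ngfr and Lgals1 lower. The list as a whole did not pass (median 0.60, camera adjusted p = 0.092). Of 11 genes of peripheral myelin and Schwann cell differentiation, 4 were higher in cOEC and 2 lower (5 and 2 adjusted over the list alone). They include myelin-associated glycoprotein Mag (2.94 ± 0.14, well above background in 6 cOEC and 1 SC channels) and the myelin enzyme Cnp (-1.31 ± 0.20). Camera gave an adjusted p of 0.062 for this list, and 0.039 without cOEC and SC replicate 1, 0.027 without a dye term and 0.048 with symbols only. Immature and repair Schwann cell genes gave 3 higher and 4 lower of 16 (3 and 5 adjusted over the list alone, camera adjusted p = 0.23). Their median was -0.089, and -0.11 within day 2, where 1 array compares the cultures without a dye term. Sox2, named by its description (-1.78 ± 0.11), was lower and the adhesion molecule Ncam1 (1.32 ± 0.20) higher. Other probes described as like Sox2, which do not stand for it in the list, had -4.51 ± 0.23 and -3.21 ± 0.15.

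Astrocyte genes were higher in cOEC as a list: 6 of 12 were higher, 1 lower and 5 not past the threshold, the same numbers adjusted over the list alone (median 0.51, camera adjusted p = 0.0013). The call was lost at an adjusted p = 0.27 with an estimated correlation. The stress-responsive protein Ndrg2 (3.07 ± 0.11), the glutamate transporter Slc1a3 (2.15 ± 0.26), glutamine synthetase (Glul, 2.07 ± 0.16) and Fgfr3 (1.60 ± 0.13) rose most. Microglia and macrophage genes gave 2 higher and 0 lower of 12 (3 and 0 adjusted over the list alone), with complement C1qb (2.41 ± 0.18) and osteopontin Spp1 (2.31 ± 0.28) higher. That list passed camera (median 0.14, adjusted p = 0.025), with an adjusted p = 0.28 with an estimated correlation, and missed it without cOEC and SC replicate 3 (adjusted p = 0.053).

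Of 14 fibroblast genes, 3 were higher in cOEC, 1 lower and 10 not past the threshold (3 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.10). Fn1 and the actin-binding protein Tagln (2.48 ± 0.37) were higher, and S100a4 lower (-1.20 ± 0.20). Lumican (Lum), in 3 cOEC and 0 SC channels well above background, was at least 1.20-fold higher, a call (limma's adjusted p = 0.047) that ended without any 1 of 7 arrays, with adjusted p up to 0.19. Oligodendrocyte genes gave 2 higher and 2 lower of 9, the same adjusted over the list alone (camera adjusted p = 0.61), among them Cnp, the tight junction protein Cldn11 (0.47 ± 0.09) and myelin basic protein (Mbp, -0.47 ± 0.08, lower on 2 of 3 direct arrays). Neuron and synapse genes gave 0 higher and 2 lower of 22, also adjusted over the list alone, the neurofilaments Nefl and Nefm (-1.51 ± 0.36). Camera gave that list an adjusted p of 0.34, and 0.048 among genes well above background in all 18 channels. The list median was -0.047, and -0.24 within day 2. Nefm lost its call without cOEC and SC replicate 1 (-1.10) or replicate 2 (-1.58). Among 9 genes of olfactory sensory neurons, 1 was lower in cOEC, also adjusted over the list alone, the G protein subunit Gnb1 (-0.48 ± 0.11, camera adjusted p = 0.53 for the list). Its call was lost without each of the 3 direct arrays (-0.47, -0.42 and -0.46). None of 12 endothelial or 3 red blood cell genes passed limma's threshold (1 and 0 at an unadjusted p under 0.05), with camera adjusted p of 0.86 and 0.99. The vascular receptor Kdr had 0.48 ± 0.15 and haemoglobin Hba1, named by its description, 0.06 ± 0.14. The endothelial median (-0.0086) and mean (0.044) differ in sign. Without SC and nOEC replicate 3, Kdr passed (0.56, adjusted p = 0.022).

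Basement membrane genes were higher in cOEC as a list. Of 17, 8 were higher and 2 lower, also adjusted over the list alone (median 0.31, camera adjusted p = 0.011, adjusted p = 0.28 with an estimated correlation). Laminin Lamc1 (2.35 ± 0.15), collagen Col18a1 (2.13 ± 0.24) and nidogen Nid2 (1.48 ± 0.08), all named by their descriptions, were examples. The 2 lower members were laminin receptor subunits, Itgb4 (-0.83 ± 0.15) and Itga6, named by its description (-0.34), both chosen after their values were seen. The fibroblast median of 0.24 stands beside this shift. Fbln2, named by its description (1.72 ± 0.48), lost its call without any 1 of 6 arrays, with adjusted p up to 0.17. Matrix proteases and their inhibitors gave 3 higher and 0 lower of 14 (3 and 1 adjusted over the list alone), such as the inhibitor Timp2 (1.82 ± 0.14). Their camera adjusted p was 0.0998 (median 0.14). They passed with the day of extraction as a block (0.20, adjusted p = 0.012), within day 4 (0.18, adjusted p = 0.0036), without replicate 1 (adjusted p = 0.0038), without cOEC and SC replicate 1 (0.021) or cOEC and nOEC replicate 1 (0.037), without a dye term (0.039) and among genes well above background in all 18 channels (0.030). Growth factors gave 5 higher and 2 lower of 19 (6 and 3 adjusted over the list alone, camera adjusted p = 0.10, and 0.014 with symbols only). Ciliary neurotrophic factor Cntf (2.21 ± 0.15), the lymphatic growth factor Vegfc (1.79 ± 0.21) and Tgfb2 (1.27 ± 0.09) were higher. Bdnf was lower (-0.93 ± 0.24), a call lost without any 1 of 4 arrays, with adjusted p up to 0.14. Axon guidance genes gave 1 higher of 14, Mag, also adjusted over the list alone (camera adjusted p = 0.37).

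Cytokine, chemokine and innate sensing genes gave 6 higher and 2 lower of 22, also adjusted over the list alone, with Cxcl12 (1.42 ± 0.25) and Cxcl1 (1.32 ± 0.17) higher in cOEC, and Ccl2 and Ccl7, named by its description (-1.67 ± 0.35), lower. The list passed camera (median 0.16, 0.15 with bounds, adjusted p = 0.0385), with an adjusted p = 0.33 with an estimated correlation. It turned to a median of -0.088 among genes well above background in all 18 channels, and it missed the threshold without cOEC and SC replicate 2 (adjusted p = 0.084), cOEC and nOEC replicate 1 (0.056) or SC and nOEC replicate 2 (0.068). Without cOEC and SC replicate 3, Ccl7 had -1.50 and an adjusted p of 0.060. Interferon response and MHC class I genes gave 5 higher and 1 lower of 11, also adjusted over the list alone. Psmb9 (0.99 ± 0.13), an immunoproteasome subunit, and beta-2 microglobulin (B2m, 0.79 ± 0.12) were higher and the GTPase Gbp2 lower (-1.44 ± 0.17). This list also passed camera (median 0.24, adjusted p = 0.018, adjusted p = 0.28 with an estimated correlation). Immediate early genes gave 2 higher and 5 lower of 19 (3 and 8 adjusted over the list alone, camera adjusted p = 0.14), with the stress factor Atf3 (-2.18 ± 0.29, lower on 2 of 3 direct arrays) and Ier2, named by its description (-0.77 ± 0.11), lower. Of 6 MHC class II genes, 0 passed limma's threshold, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.79).

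Wnt signalling genes gave 4 higher and 0 lower of 16 (6 and 1 adjusted over the list alone), led by the receptor Fzd1 (2.16 ± 0.11) and the inhibitor Wif1 (0.59 ± 0.10). Their camera adjusted p was 0.060. They passed with no background correction (0.042), offset 0 (0.026), the scanner's log ratios (0.037), the authors' series matrix values (0.044), no dye term (0.049) and symbols only (0.0042), without cOEC and SC replicate 2 (0.030) or replicate 2 as a whole (0.028), and by fry. Forebrain and head patterning genes gave 3 higher of 12, also adjusted over the list alone (camera adjusted p = 0.11), such as the homeobox factor Alx1 (0.53 ± 0.08). Of 6 Hox genes, 1 was higher, also adjusted over the list alone (camera adjusted p = 0.29). Oxidative phosphorylation genes gave 2 higher and 4 lower of 21, also adjusted over the list alone, with a median of -0.11 that turned to 0.20 under median centring in place of loess. That list passed camera at an adjusted p of 0.035 (adjusted p = 0.28 with an estimated correlation) and missed it without cOEC and SC replicate 1 (0.11) or SC and nOEC replicate 3 (0.059). Cytochrome oxidase subunits Cox5b (-0.72 ± 0.10) and Cox5a (0.74 ± 0.12) went opposite ways. Cholesterol synthesis genes gave 1 higher and 1 lower of 15, also adjusted over the list alone (camera adjusted p = 0.86), with squalene epoxidase Sqle (1.23 ± 0.11) higher. Their median (-0.022) and mean (0.055) differ in sign. None of 22 cell cycle genes passed limma's threshold, with 0 at an unadjusted p under 0.05 and a camera adjusted p of 0.39 (median -0.11). That list turned and passed camera with the day of extraction as a block (0.17, adjusted p = 0.0086), without replicate 1 (0.13, adjusted p = 0.010) and within day 4 (0.097, adjusted p = 0.045). Each of these settings sets aside replicate 1 of cOEC and SC and of SC and nOEC, so they are not independent.

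Without cOEC and SC replicate 3, 655 genes were lower in cOEC than in SC in place of 1014, and of the 80 called results for named genes in this comparison, 15 lost their call without some array while 65 kept it without each. With the day of image extraction as a block, 1461 genes were higher and 1210 lower. Within day 2 (3 arrays, 1 direct) the counts were 310 and 154, and within day 4 (4 arrays, 1 direct) 1288 and 1149. With the day as a block, within day 2 and within day 4, the astrocyte median was 0.47, 0.66 and 0.44, and the basement membrane median 0.21, -0.063 and 0.25. In the same order, the interferon median was 0.18, 0.11 and 0.13, the microglia median 0.12, 0.14 and 0.17, the cytokine median 0.074, 0.18 and 0.037, and the oxidative phosphorylation median -0.14, -0.091 and -0.10. Days 1 and 3 hold 1 array each, so an effect of the block cannot be told there from that of leaving out the array. Within day 2, cOEC over SC rests on 1 array without a dye term, so dye and cell type cannot be told apart there. The day block ended 5 of the 6 list calls by camera, for astrocytes (adjusted p = 0.051), microglia (0.071), cytokines (0.14), interferon (0.14) and oxidative phosphorylation (0.15), and kept basement membrane (0.012). It kept 72 of the 80 calls for named genes, and the 3 direct arrays by themselves kept 31.

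Other choices ended list calls of cOEC over SC too. The basement membrane call ended with members named by a symbol only (camera adjusted p = 0.86), on the 3 direct arrays (0.18), without replicate 3 (0.086) and under median centring (0.059). Its medians there were 0.12, 0.18, 0.43 and 0.84, against 0.31. The microglia call ended among genes well above background in all 18 channels (0.17), under median centring (0.11), on the direct arrays (0.082) and without replicate 1 (0.064). Its medians there were 0.29, 0.20, 0.13 and 0.14, against 0.14. The interferon call ended in all 18 channels (0.21) and without replicate 1 (0.091). Its medians there were 0.34 and 0.21, against 0.24. The cytokine call ended in all 18 channels (0.51), under median centring (0.13), without replicate 1 (0.078) and without replicate 2 (0.11). The oxidative phosphorylation call ended under median centring (0.53), in all 18 channels (0.14), with symbols only (0.13), with the scanner's log ratios (0.11), with offset 0 (0.099), on the direct arrays (0.078) and without replicate 1 (0.14). Within day 2 the microglia (0.12), cytokine (0.25), interferon (0.93) and oxidative phosphorylation (0.47) calls were not made. The same held within day 4 for those for cytokines (0.31), interferon (0.17) and oxidative phosphorylation (0.17).

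The comparison of cOEC with nOEC asks how ensheathing cells in culture differ from those in the nerve layer. Lower in culture were prostaglandin D synthase (Ptgds, a log2 ratio of -5.69 ± 0.15), the heparin-binding growth factor pleiotrophin (Ptn, -4.90 ± 0.23) and Fabp7 (-4.33 ± 0.21). Higher in culture were A2m (4.85 ± 0.49), Ccdc80 (4.35 ± 0.16), Ccn2 (4.24 ± 0.24), annexin Anxa1 (4.05 ± 0.32) and the calcium-binding protein S100a6 (3.70 ± 0.11). In all, 2696 genes were higher in cOEC and 3346 lower, 36.0% of those tested. Median centring in place of loess turned the balance, with 3573 higher and 2478 lower, 59.0% higher in place of 44.6%.

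The other large increases were Fn1 (4.01), S100a4 (3.66) and S100a10 (3.50), the interleukin 33 receptor Il1rl1 (3.45 ± 0.52), Ramp3 (3.43), Tagln (3.20) and the peptidase Mme (3.01), with limma's adjusted p from 1.5e-07 to 0.00078 over the 12. Further large decreases were the matrix protein Ecm2 (-5.21), the phosphatase inhibitor Ppp1r1a (-5.13), the dicarboxylate transporter Slc13a3 (-4.79), Fabp5 (-4.59), insulin-like growth factor Igf2 (-4.27), the granule protein Chgb (-4.25), angiotensinogen (Agt, -4.25) and the glycolytic enzyme Aldoc (-4.20). Their adjusted p in limma were 9.8e-06 or lower. By the naming rule all 24 genes went the same way on the 3 direct arrays. Over all calls, 2342 of the 2696 higher genes and 2885 of the 3346 lower ones did so.

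Of 15 ensheathing cell markers, 7 were higher in cOEC than in nOEC and 8 lower, with 0 left under the threshold, and the counts were the same adjusted over the list alone (median -0.55, camera adjusted p = 0.48). Fabp7 and neuropeptide Y (Npy, -3.01 ± 0.49, 1 channel saturated) were lower, while vimentin (Vim, 2.79 ± 0.26), Ngfr (1.68 ± 0.25) and Sparc (1.61 ± 0.15) were higher. Mean log2 intensity of Fabp7 was 14.93 ± 0.13 (SD of 6 channels) in nOEC, 10.15 ± 0.41 in cOEC and 7.27 ± 0.93 in SC. Ngfr ran the other way between the cultures, with 7.97 ± 0.62 in nOEC, 9.68 ± 0.46 in cOEC and 12.61 ± 0.82 in SC. Peripheral myelin genes gave 5 higher and 4 lower of 11, also adjusted over the list alone (camera adjusted p = 0.88), with Pmp22 (2.94 ± 0.40) and Mag (1.82 ± 0.14) higher. Immature and repair Schwann cell genes gave 5 higher and 5 lower of 16 (6 and 6 adjusted over the list alone, camera adjusted p = 0.87), among them Jun (2.08 ± 0.34), higher, and Olig1 (-2.54 ± 0.19) and the glial filament Gfap (-1.24 ± 0.08), lower.

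**Figure D2:**
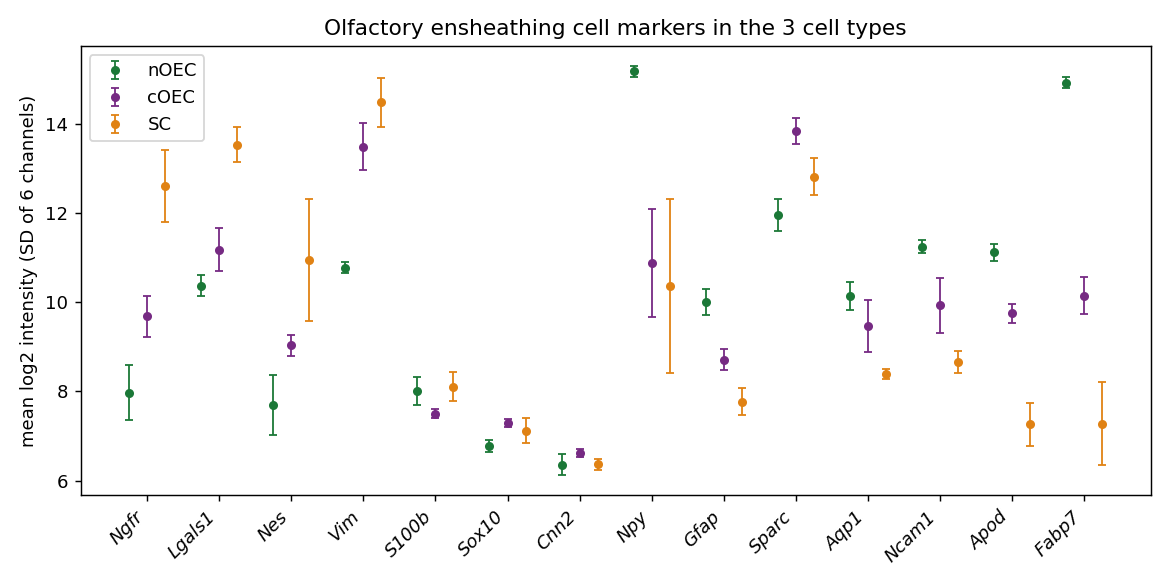
Mean log2 intensity of ensheathing cell markers in cOEC, SC and nOEC after loess and Aquantile, with the SD of 6 channels. Levels compare cell types within a gene, not genes with each other: Fabp7 falls from 14.93 in nOEC to 10.15 in cOEC and 7.27 in SC, and Ngfr is highest in SC at 12.61.

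Of 9 genes of olfactory sensory neurons, 0 were higher, 5 lower and 4 not past the threshold, also adjusted over the list alone (median -1.33, camera adjusted p = 0.0049, adjusted p = 0.21 with an estimated correlation). The odorant signalling enzyme Adcy3 (-3.57 ± 0.22) and the calcium-binding protein Calb2 (-1.90 ± 0.14) were lower. The odorant-gated channel subunit Cnga2 was at least 4.09-fold lower, in 0 of 6 cOEC channels well above background. Endothelial and pericyte genes gave 0 higher and 9 lower of 12, also adjusted over the list alone (median -0.57, camera adjusted p = 0.00031, adjusted p = 0.21 with an estimated correlation), with Kdr (-3.85 ± 0.15) and the tight junction protein Cldn5, named by its description (-3.53 ± 0.24), as examples. Microglia and macrophage genes gave 0 higher and 8 lower of 12, also adjusted over the list alone (median -0.62, camera adjusted p = 0.00095, adjusted p = 0.21 with an estimated correlation), such as the MHC class II chaperone Cd74 (-1.83 ± 0.20) and lysozyme Lyz2 (-1.36 ± 0.19). Of 3 red blood cell genes, 2 were lower, also adjusted over the list alone (median -0.95, camera adjusted p = 0.12, and 0.048 within day 2), Hba1, named by its description (-1.79 ± 0.14), and the haem synthesis enzyme Alas2 (-0.95 ± 0.11).

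Astrocyte genes gave 1 higher and 8 lower of 12 (1 and 9 adjusted over the list alone, median -0.76, camera adjusted p = 2.8e-04, adjusted p = 0.24 with an estimated correlation), with Aldoc, the gap junction protein Gjb6 (-3.65 ± 0.21), Slc1a3 (-2.33 ± 0.26) and Glul (-1.99 ± 0.16) lower. Oligodendrocyte genes gave 1 higher and 6 lower of 9, also adjusted over the list alone (median -0.48, camera adjusted p = 0.023, adjusted p = 0.21 with an estimated correlation), such as Olig1 and the precursor proteoglycan Cspg4 (-1.36 ± 0.22). Neuron and synapse genes gave 2 higher and 10 lower of 22, also adjusted over the list alone (median -0.17, camera adjusted p = 0.022, adjusted p = 0.28 with an estimated correlation). The synaptic protein Snap25 (-3.71 ± 0.25) and the GABA-producing enzyme Gad1 (-3.68 ± 0.22) were lower, and the neurofilaments Nefm (2.70 ± 0.36) and Nefl (2.25 ± 0.28) higher.

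Immediate early genes were higher in cOEC than in nOEC: 11 of 19 were higher, 1 lower and 7 not past the threshold (12 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.00060, adjusted p = 0.21 with an estimated correlation). Atf3 (2.66 ± 0.28), Jun and Fos, named by its description (1.56 ± 0.32), led them. Basement membrane genes gave 8 higher and 1 lower of 17, also adjusted over the list alone (median 0.39, camera adjusted p = 0.011, adjusted p = 0.28 with an estimated correlation), with Col18a1 (2.56 ± 0.24) and Lamc1 (2.20 ± 0.15), both named by their descriptions, higher and Itgb4 (-2.96 ± 0.15) lower. Matrix proteases and inhibitors gave 6 higher and 0 lower of 14 (7 and 0 adjusted over the list alone, median 0.29, 0.27 with bounds, camera adjusted p = 0.011, adjusted p = 0.37 with an estimated correlation), such as the aggrecan-cleaving protease Adamts1 (2.90 ± 0.25) and the plasminogen activator Plat (1.67 ± 0.21). Fibroblast genes, the markers of another matrix-making cell, gave 6 higher and 3 lower of 14 (6 and 4 adjusted over the list alone, median 0.19, 0.17 with bounds, camera adjusted p = 0.12), with the collagen Col1a2 (1.68 ± 0.36) higher. They passed among genes well above background in all 18 channels (1.04, adjusted p = 0.030), on the 3 direct arrays (0.24, adjusted p = 0.040), within day 2 (0.21, adjusted p = 1.4e-04) and with symbols only (1.68, adjusted p = 0.0020). Growth factors gave 7 higher and 5 lower of 19 (8 and 6 adjusted over the list alone), from Vegfc (1.46 ± 0.21) and Tgfb2 (1.22 ± 0.09) to Igf2 and Ptn. Their median of 0.18 and mean of -0.32 differ in sign (camera adjusted p = 0.76). Axon guidance and growth inhibition genes gave 1 higher and 3 lower of 14, also adjusted over the list alone (camera adjusted p = 0.80), with the proteoglycan Bcan lower (-2.01 ± 0.14).

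Oxidative phosphorylation genes were lower in cOEC, 12 of 21 with 0 higher, also adjusted over the list alone (median -0.33, camera adjusted p = 0.00040, adjusted p = 0.21 with an estimated correlation). Under median centring the median turned to 0.12 (camera adjusted p = 0.79). The complex I subunit Ndufa5 (-1.42 ± 0.10) and the cytochrome oxidase subunit Cox6c (-1.13 ± 0.09) were lower. MHC class II genes gave 0 higher and 3 lower of 6, also adjusted over the list alone (median -0.37, -0.27 with bounds, camera adjusted p = 0.046, adjusted p = 0.25 with an estimated correlation), among them Cd74 and RT1-Da, named by its description (-0.90 ± 0.14). That list missed the threshold without cOEC and nOEC replicate 2 (adjusted p = 0.077), cOEC and nOEC replicate 3 (0.065) or SC and nOEC replicate 3 (0.054). Interferon and MHC class I genes gave 2 higher and 7 lower of 11, also adjusted over the list alone (median -0.38, camera adjusted p = 0.079, and 0.041 without cOEC and nOEC replicate 1 and 0.049 with no filter on dim probes), such as the antiviral enzyme Oas1a (-1.27 ± 0.14). Cytokine and chemokine genes gave 4 higher and 5 lower of 22 (4 and 6 adjusted over the list alone, camera adjusted p = 0.87), with the adhesion molecule Vcam1 (-3.92 ± 0.28) and the chemokines Cx3cl1 (-2.47 ± 0.34) and Cxcl12 (-1.52 ± 0.25) lower. Cholesterol synthesis gave 1 higher and 5 lower of 15, also adjusted over the list alone (camera adjusted p = 0.23), with Hmgcs1 (-1.86 ± 0.08) lower. Wnt signalling gave 7 higher and 4 lower of 16, also adjusted over the list alone (camera adjusted p = 0.17, and 0.014 with symbols only), from Ccn4 (1.09 ± 0.19) to Wnt5b, named by its description (-1.54 ± 0.14). Forebrain patterning genes gave 2 lower of 12, also adjusted over the list alone (camera adjusted p = 0.86), among them Pax6 (-0.40 ± 0.07, lower on 2 of 3 direct arrays). Of 6 Hox genes, 0 passed limma's threshold and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.46). Cell cycle genes gave 2 higher of 22, and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.15). They passed with the day of extraction as a block (0.19, adjusted p = 0.021), within day 2 (0.27, adjusted p = 0.026), on the 3 direct arrays (0.29, adjusted p = 0.0015), without replicate 1 (0.25, adjusted p = 0.0075) and without cOEC and SC replicate 1 (0.30, adjusted p = 0.023).

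Of 99 called results for named genes in this comparison, 95 kept their call without each array and 4 lost it without some array. With the day of extraction as a block, 3081 genes were higher in cOEC than in nOEC and 3717 lower, with 640 and 1092 within day 2 (2 direct arrays) and 2182 and 2945 within day 4 (1 direct array). With the day as a block, within day 2 and within day 4, medians were -1.32, -1.23 and -1.44 for olfactory sensory neurons, -0.54, -0.52 and -0.50 for endothelial cells, and -0.63, -0.55 and -0.65 for microglia. In the same order, they were -0.75, -0.89 and -0.61 for astrocytes, -0.47, -0.48 and -0.50 for oligodendrocytes, -0.16, -0.19 and -0.082 for neurons and -0.39, -0.38 and -0.29 for MHC class II. Immediate early genes had 0.39, 0.28 and 0.34, basement membrane genes 0.51, 0.29 and 0.53, matrix proteases 0.30, 0.14 and 0.28, and oxidative phosphorylation genes -0.32, -0.31 and -0.32. Of 11 list calls by camera, the day block ended that for MHC class II (adjusted p = 0.052), which was also not made within day 2 (0.058) or day 4 (0.050), and within day 4 the neuron call was not made (0.11).

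For cOEC over nOEC, members named by a symbol only ended the calls for basement membrane (camera adjusted p = 0.67), MHC class II (0.13) and neurons (0.061). Among genes well above background in all 18 channels, those for neurons (0.65), MHC class II (0.37), oligodendrocytes (0.27) and basement membrane (0.12) ended. Their medians there were -0.14, -0.94, -0.48 and 0.60, against -0.17, -0.37, -0.48 and 0.39, with fewer genes tested. The neuron call also ended without replicate 1 (0.071), and the MHC class II call without a dye term (0.064), replicate 2 (0.069) or replicate 3 (0.070).

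The comparison of SC with nOEC sets cultured nerve glia beside the native olfactory nerve layer. Schwann cells had more RNA for the fibroblast and glial calcium-binding protein S100a4 (4.86 ± 0.20), the injury-induced factor Atf3 (4.85 ± 0.26), the neurofilaments Nefl (4.53 ± 0.28) and Nefm (4.21 ± 0.36), and Ngfr (4.46 ± 0.25). They had far less RNA for the detoxifying enzyme Gsta1 (-7.31 ± 0.23), Fabp7 (-7.31 ± 0.21) and the matricellular protein Sparcl1 (-7.17 ± 0.28). In all, 2695 genes were higher in SC and 3582 lower, 37.4% of those tested.

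Other large increases were S100a10 (4.03), the GDNF receptor Gfra1 (4.0 ± 0.33), vimentin (Vim, 3.73), the proteoglycan Gpc1 (3.66), the actin nucleation subunit Arpc1b (3.55), the hyaluronan receptor Cd44 (3.47) and galectin Lgals3 (3.46), with limma's adjusted p from 3.7e-07 to 3.8e-05 over the 12. Large decreases also held Ptgds (-5.87), Ptn (-5.59), Aldoc (-5.22), Ecm2 (-5.18), the acyl-CoA synthetase Acsbg1 (-5.13), the growth factor binding protein Igfbp2 (-4.97), Slc13a3 (-4.67) and Igf2 (-4.62), with limma's adjusted p of 1.7e-06 or lower for those named. The naming rule required all 24 genes to go the same way on the 3 direct arrays. Over all calls, 2056 of the 2695 higher genes and 3150 of the 3582 lower ones did so.

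Ensheathing cell markers gave 6 higher and 7 lower of 15, also adjusted over the list alone. Their median (0.0094) and mean (-0.64) differ in sign (camera adjusted p = 0.50), with Fabp7 and Apod (-3.78 ± 0.15) lower in SC. Myelin genes gave 3 higher and 5 lower of 11, also adjusted over the list alone (camera adjusted p = 0.33), with Cnp (1.89 ± 0.20) higher and the gap junction protein Gjb1 (-1.34 ± 0.06) lower. Immature and repair Schwann cell genes gave 5 higher and 4 lower of 16, also adjusted over the list alone (camera adjusted p = 0.32), among them Ngfr and Jun (3.11 ± 0.34), higher, and Ncam1 (-2.50 ± 0.20), lower.

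Olfactory sensory neuron genes gave 0 higher and 5 lower of 9, also adjusted over the list alone (median -1.22, camera adjusted p = 0.0089, adjusted p = 0.21 with an estimated correlation), such as Adcy3 (-3.71 ± 0.22) and Calb2 (-1.75 ± 0.14). Olfactory marker protein (Omp) was at least 2.42-fold lower, in 0 of 6 SC channels well above background. Endothelial genes gave 0 higher and 8 lower of 12, also adjusted over the list alone (median -0.75, -0.67 with bounds, camera adjusted p = 0.00060, adjusted p = 0.21 with an estimated correlation), with Kdr at -4.33 ± 0.15. Microglia and macrophage genes gave 0 higher and 10 lower of 12, also adjusted over the list alone (median -1.02, camera adjusted p = 0.00011, adjusted p = 0.21 with an estimated correlation), with C1qb at -3.47 ± 0.18. Red blood cell genes gave 2 lower of 3, also adjusted over the list alone (camera adjusted p = 0.15), with Alas2 at -0.96 ± 0.11. Their median was -0.96, and -1.24 within day 2. Astrocyte genes gave 0 higher and 9 lower of 12, also adjusted over the list alone (median -1.38, camera adjusted p = 3.2e-05, adjusted p = 0.21 with an estimated correlation), led by Aldoc, Slc1a3 (-4.47 ± 0.26) and Glul (-4.06 ± 0.16). Oligodendrocyte genes gave 1 higher and 6 lower of 9, also adjusted over the list alone (median -0.51, camera adjusted p = 0.028, adjusted p = 0.21 with an estimated correlation), including Olig1 (-2.45 ± 0.19). The growth factor receptor Pdgfra, named by its description, was at least 3.54-fold lower, in 0 of 6 SC channels well above background. Neuron and synapse genes gave 2 higher and 10 lower of 22, also adjusted over the list alone, with Snap25 (-3.64 ± 0.25) and Gad1 (-3.57 ± 0.22) lower. That list passed camera (median -0.20, -0.042 among genes well above background in all 18 channels, adjusted p = 0.039, adjusted p = 0.28 with an estimated correlation), but not without cOEC and SC replicate 3 (0.053) or SC and nOEC replicate 1 (0.050).

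Immediate early genes were higher in SC: 12 of 19 were higher and 1 lower (13 and 1 adjusted over the list alone, median 0.39, camera adjusted p = 2.8e-04, adjusted p = 0.21 with an estimated correlation), with Atf3, Jun, Fos (2.22 ± 0.32) and Ier2 (1.59 ± 0.11) ahead, the latter pair named by their descriptions. Of 22 cell cycle genes, 0 passed limma's threshold or did so adjusted over the list alone, and 6 had an unadjusted p under 0.05. That list still passed camera (median 0.27, adjusted p = 0.047, adjusted p = 0.65 with an estimated correlation), but not without SC and nOEC replicate 1 (0.32), cOEC and SC replicate 1 (0.051), or cOEC and nOEC replicates 2 (0.067) or 3 (0.070). It did not pass fry either (adjusted p = 0.18). Fibroblast genes gave 3 higher and 4 lower of 14, also adjusted over the list alone, with Col1a2 (2.81 ± 0.36) higher. Their median (-0.056) and mean (0.35) differ in sign (camera adjusted p = 0.94). Basement membrane genes gave 3 higher and 3 lower of 17, also adjusted over the list alone, such as Sparc (0.72 ± 0.15) and Itgb4 (-2.13 ± 0.15), with a median of 0.073 and a mean of -0.11 (camera adjusted p = 0.86). Matrix proteases and inhibitors gave 6 higher and 1 lower of 14, also adjusted over the list alone (camera adjusted p = 0.12, and 0.019 on the 3 direct arrays), with Adamts1 (1.87 ± 0.25) higher and Timp2 (-1.43 ± 0.14) lower. Growth factors gave 4 higher and 6 lower of 19, also adjusted over the list alone (camera adjusted p = 0.37, and 0.030 among genes well above background in all 18 channels), with neurturin (Nrtn), named by its description (1.52 ± 0.22), higher and Cntf (-1.77 ± 0.15) lower. Axon guidance genes gave 1 higher and 5 lower of 14, also adjusted over the list alone (camera adjusted p = 0.21, and 0.047 with symbols only), with Bcan (-1.95 ± 0.14) and Cspg4 (-1.57 ± 0.22) lower.

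Interferon and MHC class I genes were lower in SC, 8 of 11 with 1 higher, also adjusted over the list alone (median -0.53, camera adjusted p = 0.0055, adjusted p = 0.27 with an estimated correlation). Psmb9 (-1.57 ± 0.13) and B2m (-1.52 ± 0.12) were lower, and Gbp2 (2.13 ± 0.17) higher. Cytokine and chemokine genes gave 1 higher and 7 lower of 22, also adjusted over the list alone (camera adjusted p = 0.23), with Ccl2 (3.09 ± 0.28) higher and Cx3cl1 (-3.72 ± 0.34) lower. Vcam1 was at least 16.0-fold lower, in 0 of 6 SC channels well above background. MHC class II genes gave 4 lower of 6, also adjusted over the list alone (camera adjusted p = 0.092), with Cd74 at -1.72 ± 0.20. Oxidative phosphorylation genes gave 2 higher and 11 lower of 21, also adjusted over the list alone (median -0.39, camera adjusted p = 0.0385, adjusted p = 0.28 with an estimated correlation, and 0.051 by the preset test without cOEC and SC replicate 3), with Ndufa5 (-1.32 ± 0.10) and the succinate dehydrogenase subunit Sdha (-0.88 ± 0.10) lower. Cholesterol synthesis gave 1 higher and 7 lower of 15 (2 and 8 adjusted over the list alone, camera adjusted p = 0.14, and 0.048 with symbols only), with Sqle (-1.13 ± 0.11) lower. Wnt signalling gave 3 higher and 4 lower of 16 (3 and 5 adjusted over the list alone, camera adjusted p = 0.87), with Fzd1 lower (-1.35 ± 0.11), and its median (0.036) and mean (-0.15) differ in sign. Forebrain patterning genes gave 4 lower of 12, also adjusted over the list alone (camera adjusted p = 0.26), such as Pax6 (-0.54 ± 0.07). Hox genes gave 1 higher and 1 lower of 6, also adjusted over the list alone (camera adjusted p = 0.81), and their median (-0.028) and mean (0.012) differ in sign. Hoxb2, named by its description (0.75 ± 0.22), was higher, a call lost without SC and nOEC replicates 2 (0.61, limma's adjusted p = 0.10) or 3 (0.78, adjusted p = 0.059).

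**Figure D3:**
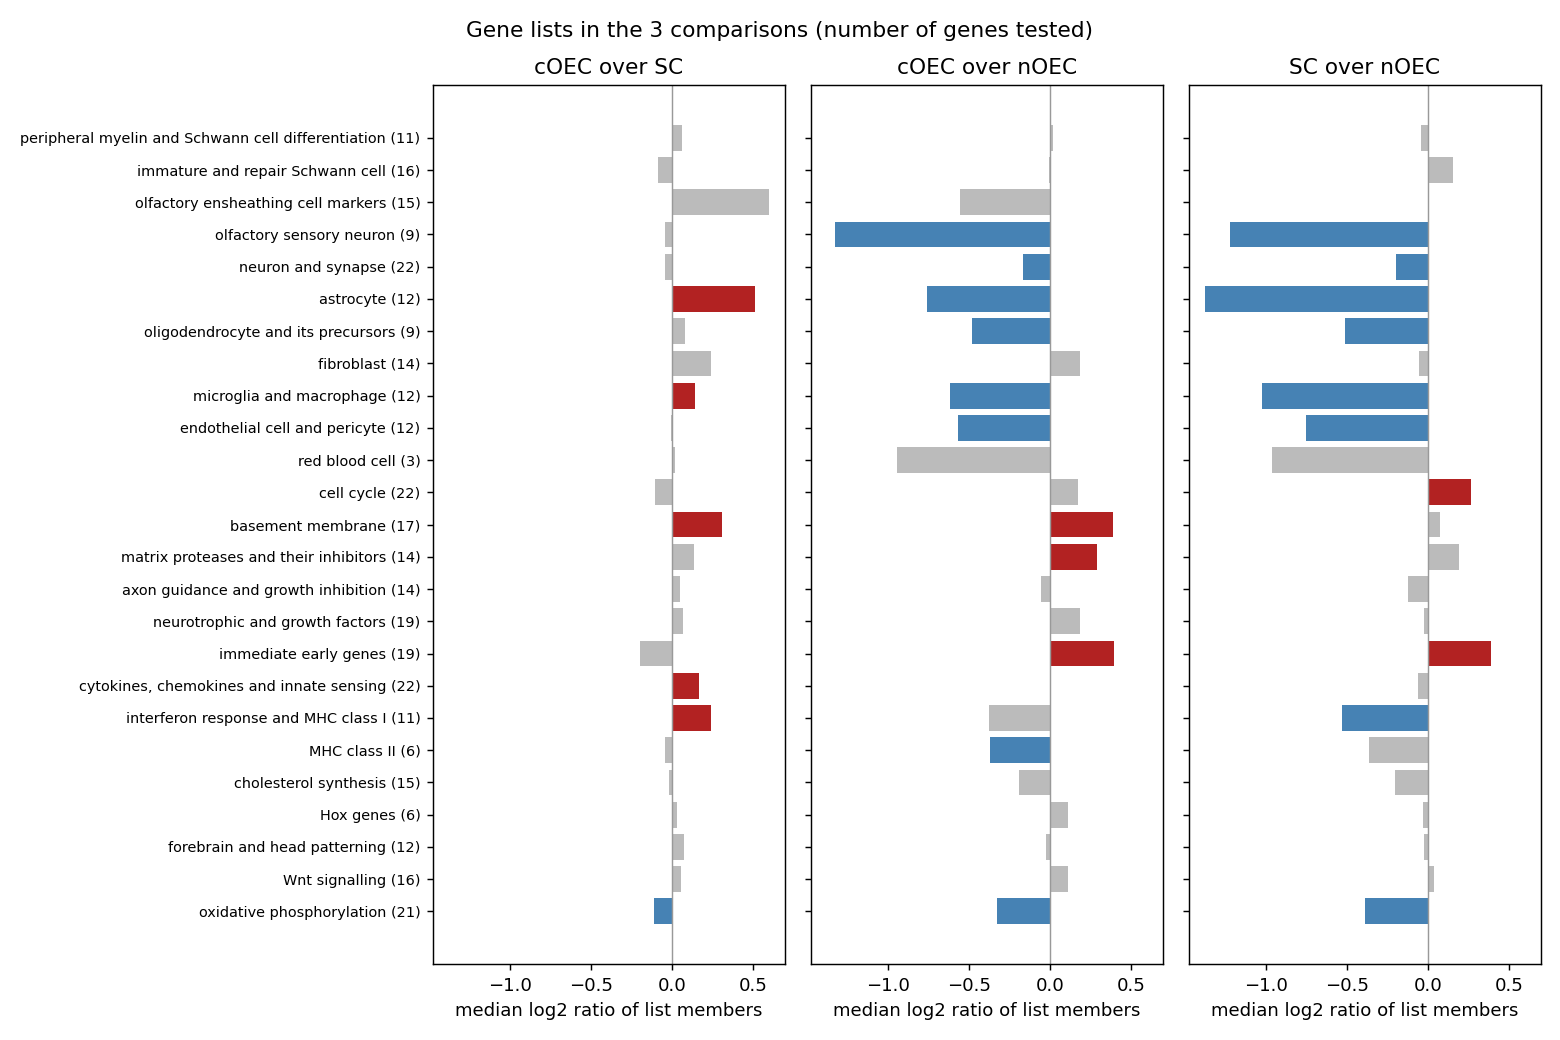
Median log2 ratio of each gene list in the 3 comparisons, coloured where camera's adjusted p was under 0.05 with the preset correlation and grey elsewhere; with an estimated correlation 0 of the 75 tests passed. Medians of olfactory sensory neuron genes over nOEC were -1.33 in cOEC and -1.22 in SC (adjusted p = 0.21 with an estimated correlation in both), those of immediate early genes 0.40 and 0.39 (0.21 in both), and the oxidative phosphorylation medians of cOEC over SC (-0.11) and over nOEC (-0.33) turned to 0.20 and 0.12 under median centring.

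Of 100 called results for named genes in SC against nOEC, 95 kept their call without each array and 5 lost it without some array. With the day of extraction as a block, 2344 genes were higher in SC than in nOEC and 3218 lower, with 212 and 615 within day 2, where the comparison is indirect, and 2229 and 3214 within day 4 (2 direct arrays). With the day as a block, within day 2 and within day 4, medians were -1.07, -1.13 and -1.11 for olfactory sensory neurons, -0.58, -0.47 and -0.62 for endothelial cells, and -1.0, -0.87 and -1.01 for microglia. In the same order they were -1.33, -1.42 and -1.25 for astrocytes, -0.55, -0.16 and -0.56 for oligodendrocytes, -0.20, 0.020 and -0.16 for neurons, and -0.41, -0.31 and -0.50 for interferon genes. Immediate early genes had 0.38, 0.49 and 0.38, cell cycle genes 0.035, 0.12 and 0.085, and oxidative phosphorylation genes -0.38, -0.35 and -0.40. Within day 2, SC over nOEC passes through 1 array of cOEC and SC without a dye term, so dye and cell type cannot be told apart there. The day block ended 4 of the 10 list calls by camera, for oligodendrocytes (adjusted p = 0.051), neurons (0.053), cell cycle (0.70) and oxidative phosphorylation (0.051). Within day 2 the calls for neurons (0.80), cell cycle (0.52), interferon (0.42) and oxidative phosphorylation (0.12) were not made. The same held within day 4 for those for neurons (0.079), cell cycle (0.51) and oxidative phosphorylation (0.069).

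For SC over nOEC, members named by a symbol only ended the calls for cell cycle (camera adjusted p = 0.34), neurons (0.12) and oligodendrocytes (0.060). Among genes well above background in all 18 channels, those for neurons (0.88), oligodendrocytes (0.78), cell cycle (0.30), interferon (0.15) and olfactory sensory neurons (0.10) ended. Their medians there were -0.042, -0.011, 0.23, -0.97 and -1.22, against -0.20, -0.51, 0.27, -0.53 and -1.22, with fewer genes tested. Without replicate 1, those for cell cycle (0.21), neurons (0.091) and oligodendrocytes (0.067) ended. The oxidative phosphorylation call ended under median centring (0.41), with offset 0 (0.066), with the scanner's log ratios (0.052), without replicate 2 (0.064) and without replicate 3 (0.055). The cell cycle call ended under median centring (0.13), on the 3 direct arrays (0.080) and with the scanner's log ratios (0.050). The neuron call ended on the direct arrays (0.10) and without a dye term (0.075).

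The 2 cultures differed from nOEC in the same direction for 4272 genes: 1556 were higher in both, where independent lists of the same sizes would share 432, and 2716 lower in both, where they would share 713. A further 188 genes were called in opposite directions. Both comparisons share the nOEC samples and the same dissected tissue. RNA of tissue cells absent from both cultures would count as lower in both. The numbers for independent lists are therefore no test of a shared response to culture. Simulated unchanged cell types gave an overlap of 0 in each direction, but with no gene changed there was next to nothing to call. That 0 therefore does not measure how far shared samples add to the overlap. The simulations also drew noise separately for each array, so they hold no RNA shared between arrays. Across genes, the log2 ratios of the 2 comparisons had a Pearson's r of 0.784 and a covariance of 0.3185, against 0.502 and 0.0062 in the simulations, a difference in covariance of 0.3123. Taken from direct arrays of different replicate numbers, in 6 ways with 1 array for 1 comparison and 2 for the other, r was 0.654 to 0.775 and the covariance 0.225 to 0.404. Ptgds, Ptn, Ecm2, Slc13a3, Igf2, Aldoc and Fabp7 were among the 12 largest decreases in both cultures, and S100a4 and S100a10 among the 12 largest increases in both.

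The deposited tables of the authors called 1625 probes between SC and cOEC (630 higher and 995 lower in SC) and 4021 between nOEC and cOEC (2361 and 1660). Their log2 ratios, turned to the same direction, had an r of 0.995 and 0.997 across genes with the fit used here. Both called 1600 and 3961 genes, with 0 in opposite directions.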

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

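Counts of called genes kept their size, within 1.5-fold, with no background correction, normexp with offset 0, the scanner's log ratios, the authors' series matrix values, no filter on dim probes, every probe counted, arrayWeights and the day of extraction as a block. With the day block, however, 17 of the 27 list calls held. Loess followed by Aquantile gives the same log ratios by construction. A separate-channel fit also kept all 7 gene counts and gives no list tests, as do the other thresholds. The slide was not tried apart from the day of extraction. Requiring all 18 channels to be well above background drops genes that are dim in 1 cell type by construction. It left 1993 genes lower in cOEC than in nOEC, 2004 lower in SC and 2712 changed the same way, with fewer genes tested. Of the 3902 main calls of cOEC over nOEC among the genes kept, 3866 held under that filter. There the cytokine list of cOEC over SC turned to a median of -0.088, and the neuron list of SC over nOEC shrank from -0.20 to -0.042. The cause was not tested.

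Median centring in place of loess gave 1965 genes higher and 523 lower in cOEC than in SC, and 3573 and 2478 in cOEC than in nOEC, where the balance turned. It also turned the oxidative phosphorylation median in both comparisons (0.20 and 0.12), and Msmo1 to 0.094 in the former. Without a dye term 1790 genes were higher in cOEC and 1696 higher in SC than in nOEC. For both choices the cause was not tested. With only the 3 direct arrays, 237 genes were higher and 95 lower in cOEC than in SC, 1460 and 2137 in cOEC than in nOEC, 845 and 1796 in SC than in nOEC, and 1896 changed the same way, with fewer arrays.

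Stricter calls give fewer genes by construction. Requiring at least 2-fold left 397 higher and 174 lower in cOEC than in SC, 423 and 849 in cOEC than in nOEC, 362 and 1067 in SC than in nOEC, and 877 changed the same way. An adjusted p under 0.01 left 895 and 588 in cOEC than in SC, 1664 higher in cOEC than in nOEC, 1642 higher in SC than in nOEC and 2757 changed the same way.

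Leaving out 1 array or all arrays of 1 replicate number gave 692 to 1456 genes higher and 426 to 1184 lower in cOEC than in SC, 1285 to 2776 and 1930 to 3467 in cOEC than in nOEC, 1310 to 2576 and 2382 to 3489 in SC than in nOEC, and 2136 to 4328 changed the same way. The lowest of each were without replicate 2, which leaves 6 arrays of 1 dye orientation. Without replicate 3 there were 801 and 460 in cOEC than in SC and 1605 higher in cOEC than in nOEC, with fewer arrays. Without cOEC and SC replicate 3 alone, 655 were lower in cOEC than in SC. Without replicate 1, the cell cycle list of cOEC over SC turned to a median of 0.13 (camera adjusted p = 0.010) and without replicate 2 it was -0.26. It was 0.17 with the day of extraction as a block (0.0086) and 0.097 within day 4 (0.045). These settings are not independent, since each sets aside replicate 1 of cOEC and SC and of SC and nOEC. The cause was not tested.

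The labels do not say that a replicate number marks shared samples, and residuals do not settle it. Those of 9 same-numbered pairs of comparisons had an r of -0.32 to 0.57 (median 0.21, against 0 with no sharing, 6 above 0.1, with 0.52, 0.57 and 0.18 for the pairs sharing SC), and those of 18 different-numbered pairs -0.58 to 0.36 (median -0.18, against -0.333). Arrays correlated best with their own number in 13 of 18 cases, against 12 expected with no sharing. The mean square between numbers was 1.89 times that of loop closure, against 1 with no sharing. That ratio and the pairs sharing SC lean towards shared samples. The calls made without a block may then be too many. Blocking on the number gave 641 higher and 405 lower in cOEC than in SC and 1625 higher in SC than in nOEC, 24 of 27 list calls held (not MHC class II in cOEC over nOEC, nor neurons and oxidative phosphorylation in SC over nOEC), 1 was made (cell cycle in cOEC over nOEC), and so did 58 of 80, 99 of 99 and 96 of 100 calls for named genes in the 3 comparisons. The block takes up degrees of freedom. Genes changed the same way against nOEC, counted from direct arrays of different replicate numbers, were 3578, 996, 983, 609, 931 and 717 in place of 4272, with fewer arrays. In each, 1 comparison rests on 1 array, assumed to vary like the 2 of the other, which alone give the spread.

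Camera with an estimated correlation called 0 of 75 list tests in place of 27, while fry, which asks if the genes of a list differ by themselves, called 57. Fry set the myelin list (median 0.021) and the growth factor list (0.18) of cOEC over nOEC in the other direction than camera. The cause was not tested.

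The remaining alternatives, lists of symbols only and the days of extraction by themselves, were chosen after seeing the data. With symbols only, 57 list tests kept their label, 7 calls were made and 8 calls ended. Those that ended were basement membrane and oxidative phosphorylation in cOEC over SC, basement membrane, neurons and MHC class II in cOEC over nOEC, and neurons, oligodendrocytes and cell cycle in SC over nOEC. Within day 2, 310 genes were higher and 154 lower in cOEC than in SC, 640 and 1092 in cOEC than in nOEC, 212 and 615 in SC than in nOEC, and 635 changed the same way, with 3 arrays and, to leave a degree of freedom, no dye term. RT1-Db1 in SC over nOEC, named by its description, was 0.094 there.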

Other observations

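Probes without a gene symbol held some of the largest differences, and the ones given here were chosen after their values were seen. By their descriptions, cOEC had more RNA than SC for sequences like pigment epithelium-derived factor, a secreted neurotrophic serpin (4.45 ± 0.16), dopachrome tautomerase, a melanin synthesis enzyme of neural crest lineages (4.09 ± 0.16, and 3.24 ± 0.16 over nOEC), P-cadherin (3.95 ± 0.18) and collagen XI alpha 1 (3.55 ± 0.25). Schwann cells had more for a beta-tubulin (-3.55 ± 0.19) and for 2 probes like Sox2, a transcription factor of immature glia (-4.51 ± 0.23 and -3.21 ± 0.15). The first of them was also higher in SC than in nOEC (3.47 ± 0.23).

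Against nOEC, both cultures had less RNA for Hes5, a Notch target that holds glia undifferentiated (-5.06 ± 0.23 in cOEC, -5.31 ± 0.23 in SC), and for plasticity related gene 1 (-4.93 ± 0.28 and -5.57 ± 0.28). A sequence like retinoic acid receptor responder 2 was lower in SC than in nOEC (-4.87 ± 0.25) and higher in cOEC than in SC (4.02 ± 0.25). Schwann cells had more RNA than nOEC for epithelial membrane protein 1 (3.87 ± 0.19), a fos-related antigen (3.74 ± 0.19) and Hsp70-3 (2.95 ± 0.10).

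All tests of explanations below were chosen after the results were seen. Of the members of the olfactory sensory neuron, endothelial and red blood cell lists, 16 were lower than in nOEC in either culture and 15 in both, with medians of -1.75 in cOEC and -1.49 in SC. Camera called the first 2 lists in both cultures (adjusted p = 0.21 with an estimated correlation), but not the red blood cell list (adjusted p = 0.12 and 0.15, and 0.048 within day 2 for cOEC). If they mark other cells in the dissected layer, the 2 cultures should hardly differ. The median size of the cOEC over SC ratio was 0.10 (0.1034), with 1 member past the threshold. Other cells could account for this pattern, but a loss of RNA shared by both cultures would give the same. The members were picked for being lower in a culture, so this test cannot tell these apart. The 3 lists were also chosen after their cOEC over SC results had been seen. Astrocyte and microglia genes, left out here, were also lower in both cultures as lists, with cOEC over SC medians of 0.51 and 0.14. The medians of the 3 lists in either culture stayed between -1.44 and -0.47 (-0.4737) with the day of extraction as a block, within day 2 and within day 4. The fall was thus present within a day. This is a weak test of the day, since both cell types of a direct comparison lie on 1 array and share its day. For the neuron list in SC an effect of the day cannot be told, since its medians ran from -0.20 to 0.020 (0.01962). The latter is the value within day 2, where dye and cell type cannot be told apart either.

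Basement membrane genes were higher in cOEC than in SC as a list (camera adjusted p = 0.011, adjusted p = 0.28 with an estimated correlation). Within day 2, where dye and cell type cannot be told apart, their median was -0.063, although camera's call was not reversed. Fibroblasts in the cOEC cultures might also make the list higher. The median of 14 fibroblast genes was 0.24 (0.2399), with an order-statistic interval of -0.074 to 0.57 at 98.7% confidence, 3 higher and 1 lower, so the test cannot tell. Lum and Pdgfra, named by its description, were the 2 members well above background in at least 3 cOEC channels and 0 SC channels, singled out after their values were seen, and the call for Lum ended without any 1 of 7 arrays.

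Astrocyte list genes were higher in cOEC than in SC (camera adjusted p = 0.0013), a call lost with an estimated correlation (adjusted p = 0.27) and with the day of extraction as a block (0.051). Astrocytes carried into the cOEC cultures with their tissue profile would keep a like share of the nOEC level of each gene, but over 9 genes lower in SC the share ran from 51.5 ± 4.6% for Ndrg2, 26.0 ± 3.4% for Gfap and 20.4 ± 3.0% for Glul to 2.82 ± 0.50% for Aldoc and -8.92 ± 17.2% for Aldh1l1. Among members under their nOEC level the spread was 60.4 (60.41) ± 17.8 percentage points, and Fgfr3 stood above it at 444 ± 61%. The share takes all nOEC signal above the SC level as that of astrocytes, which was not tested, since ensheathing cells may have their own. The spread thus does not exclude unchanged astrocytes. Astrocytes altered by culture could also give it, and cell type is confounded with time in culture.

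Each of 100 assignments of the 9 arrays to the 3 comparisons, the real one included, was counted in the same way, and the median of the others was 0. With the real assignment among them, the number with as many genes was 4 for genes higher in cOEC than in SC (real 1395, highest other 2694) and 6 for genes lower (1014 and 2673), so for the latter chance is not excluded at 0.05. It was 1 for genes higher in cOEC than in nOEC (2696 and 2476), 1 for lower (3346 and 2071), 2 for higher in SC than in nOEC (2695 and 2773), 1 for lower (3582 and 2476) and 1 for genes changed the same way (4272 and 3420). The 5 other assignments with as many calls between cOEC and SC put arrays with nOEC in all 3 of the cOEC and SC places, so their larger counts point to the difference between culture and tissue. Those assignments do not measure chance between cOEC and SC, so the counts of 4 and 6 do not decide on it.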
